A study of Drosophila melanogaster with 17 samples.

How the data were processed

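Fat bodies of female larvae at the wandering stage of the last instar were sampled in 4 groups: wild type on the control diet (6 libraries) and on high sugar (6), and ChREBP knockdown on the control diet (3) and on high sugar (2). Per the labels' protocols, larvae were reared from hatching at 25C on semi-defined food with 0.15 M or 0.7 M sucrose, total RNA was extracted with Tripure, treated with DNase and cleaned on a column, and barcoded cDNA was made from it. The labels give 1 barcode to replicates 1 to 3 of each group and a different one to each of wild-type replicates 4 to 6, so the barcode set (shared or own) was treated as a batch. The labels state no sequencing run or date. All knockdown libraries belong to the shared set.

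Per the submitters' processing notes, reads were aligned to genome build dm3 with Bowtie 0.12.7 and TopHat 1.3.2 and quantified with Cufflinks 1.1.0. The annotation and options are not stated. The deposited matrix holds 1 column per library and its header names no unit, and the values were taken as FPKM from the tool list and from their relation to transcript length. Column totals of 29778.6 to 62263.5 are low for plain FPKM, so a further scaling that is not stated is possible. Counts were not used here, so depth per library is unknown and no counting interval or floor is given. A value of exactly 0 is described as listed at 0. Of 14659 rows 4963 were 0 in every library. No 2 columns were identical.

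Symbols are those of the deposited matrix, with the current symbol added where it differs and helps, and 13055 rows were matched to a current symbol. Values were transformed as log2(FPKM + 1), which understates changes of genes with low values. Genes with a mean of at least 1 FPKM over the 17 libraries were tested, 2383 in all, 48 of which carry no CG number. One linear model with the 4 groups and the barcode set as an additive term was fitted with limma 3.58.1 in R 4.3.3, with trended and robust empirical Bayes. The 4 pairwise comparisons and the interaction were tested 2-sided, with Benjamini-Hochberg adjustment over the tested genes within each comparison and a threshold of 0.05. Errors beside log2 changes are standard errors of the fit, and errors beside FPKM means are standard deviations over libraries. At an unadjusted p under 0.05 the 5 comparisons called 710, 458, 1538, 1528 and 1358 genes, in the order of the report. The additive set term assumes that the sets differ alike on both diets. Where this was examined, a fit with a mean for each group and set gave the diet effect within each set and a test of their difference. In the knockdown comparisons the set term is estimated from wild type alone, since every knockdown library is in the shared set. Log2 changes come from this fit, so they can differ from the ratio of the group means printed beside them, which average both sets in wild type.

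In all, 27 gene lists were written before the data were examined. They cover sugar and lipid metabolism, signalling, immunity, stress, protein synthesis and turnover, the transgenes, and markers of other tissues. Of their 518 members 514 were matched to the matrix. The list called midgut proteases here also holds other midgut genes, among the measured ones the lysozyme LysD and the lipase CG5932 (magro). The 23 lists with at least 3 measured members were tested with limma's camera, which compares a list with all other tested genes, with a preset inter-gene correlation of 0.01 and again with an estimated correlation. Limma's fry was run as well, whose directional p asks whether a list's genes move on balance 1 way and whose mixed p whether they move in either direction, without comparison to other genes. List p values were adjusted over the lists within a comparison. Each list's count of called genes was also taken with p values adjusted over the list alone.

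The genes named in the report follow a rule fixed before the data were examined. For each comparison these are dmondo and bigmax; the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 FPKM over the groups compared and, for pairwise comparisons, no overlap between the shared-barcode libraries of the 2 groups; and up to 4 members of each list with the smallest p, and all transgene genes. All genes under the first 2 parts are given, 2 of them, predicted genes without a CG number, by that description and not by name. List examples are a subset of those this last part allows, picked after their values were seen, and Lsp2, Nplp2, and CG31775, CG3348 and CG5773 in the knockdown diet comparison and the 8 other heat shock genes were chosen after their values were seen. The list counts do not depend on that choice.

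Median transcript length was available for 2298 tested genes (96.4%). After the values were seen to follow length in some libraries, each library's trend of log2 value against log length was removed by loess with a span of 0.5 and all tests were repeated. The curve was fitted over all genes of a library, whatever their level, so a change after removal is relative to genes of like length. For genes of low FPKM it can differ in sign from the change in FPKM itself. Replicate numbers were checked for pairing: over 18 pairs of libraries with the same number in different groups, correlations of their deviations from the means of each group and set ranged from -0.24 to 0.22 and 5 were over 0.1, so numbers were not used as pairs.

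The procedure was tested on simulated data of the same design with 2383 genes, 200 of them changed. Changes of 0.5, 1 and 2 on the log2 scale were recovered in 68.0%, 91.4% and 96.4% of cases for sugar in wild type, 36.2%, 69.1% and 100% for knockdown on the control diet, 17.3%, 62.5% and 94.2% for knockdown on high sugar, 15.3%, 57.6% and 83.9% for sugar in the knockdown, and 11.4%, 54.3% and 88.3% for the interaction. Between 2.94% and 5.61% of the calls were false. The simulated noise was independent between genes and the set effect was additive. The length trend, the differences of diet effect between sets and the correlation between genes were not simulated. These shares therefore apply to data that meet the model and do not give the share of false calls in the real data.

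Alternatives chosen before the data were examined were pseudocounts of 0.1 and 5, no filter, a minimum mean of 5, quantile normalization, upper quartile and median ratio scaling, no set term, wild-type replicates 4 to 6 left out, replicate number as a block, library weights, plain empirical Bayes, only the compared groups in the fit, each library left out in turn, the estimated correlation and fry. Added after seeing the data were the fit with a mean for each group and set, removal of the length trend alone and with that fit, a minimum mean of 0.1 alone and with a pseudocount of 0.1, and leaving out both high-sugar knockdown libraries. Camera tests of the difference between sets and tests of summed marker values, which used a linear model of log2 sums with a mean for each group and set, were also added after seeing the data. Alternatives planned for count tables were not run, since the values are not counts. Isoforms, sequence variants and reads themselves were not analysed here.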

Results

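Messenger RNA was measured by sequencing in 17 libraries made from the fat body, the larval organ that stores fat and glycogen and does much of the work of a liver and adipose tissue. All larvae were female and at the wandering stage of the last larval instar. They had been raised on food with 0.15 M sucrose (control diet) or 0.7 M sucrose (high sugar). Wild-type larvae carried the fat body driver cgGAL4 with UAS-Dcr2, which raises Dicer-2 to strengthen RNA interference. Knockdown larvae carried in addition an RNA interference construct against ChREBP, the sugar-sensing transcription factor called Mondo (or Mio) in flies and listed here as dmondo. There were 6 wild-type libraries on each diet, 3 knockdown libraries on the control diet and 2 on high sugar, which the labels call biological replicates. Replicates 1 to 3 of each group shared 1 barcode per group and include every knockdown library (the shared-barcode set). Wild-type replicates 4 to 6 had a barcode each (the own-barcode set). The deposited values name no unit and were taken as FPKM, so read depth is unknown. The values of a library summed to between 29778.6 and 62263.5, and between 6500 and 8360 of the 14659 listed genes were above 0.

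The knockdown target was checked first. The mean value of dmondo (CG18362) was 1.47 ± 0.283 FPKM in wild type on the control diet (SD, n = 6) and 2.51 ± 0.385 on high sugar (SD, n = 6). In the knockdown it was 0.439 ± 0.116 (SD, n = 3) on the control diet and 0.236 ± 0.0696 (SD, n = 2) on high sugar, and every knockdown library lay below every wild-type library. On the log2(FPKM + 1) scale, which understates the change of genes as low as this one, dmondo fell by 0.89 ± 0.10 (SE) in the knockdown on the control diet (limma adjusted p = 2.3e-05) and by 1.62 ± 0.11 on high sugar (adjusted p = 4.7e-08), or by 0.76 on high sugar (adjusted p = 7.2e-05) with each library's trend with transcript length removed. High sugar raised dmondo in wild type by 0.51 ± 0.07 (adjusted p = 0.00037). Its binding partner bigmax differed by -0.13 ± 0.13 (adjusted p = 0.61) and 0.27 ± 0.15 (adjusted p = 0.12) between knockdown and wild type on the 2 diets and was not called.

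**Figure D1:**
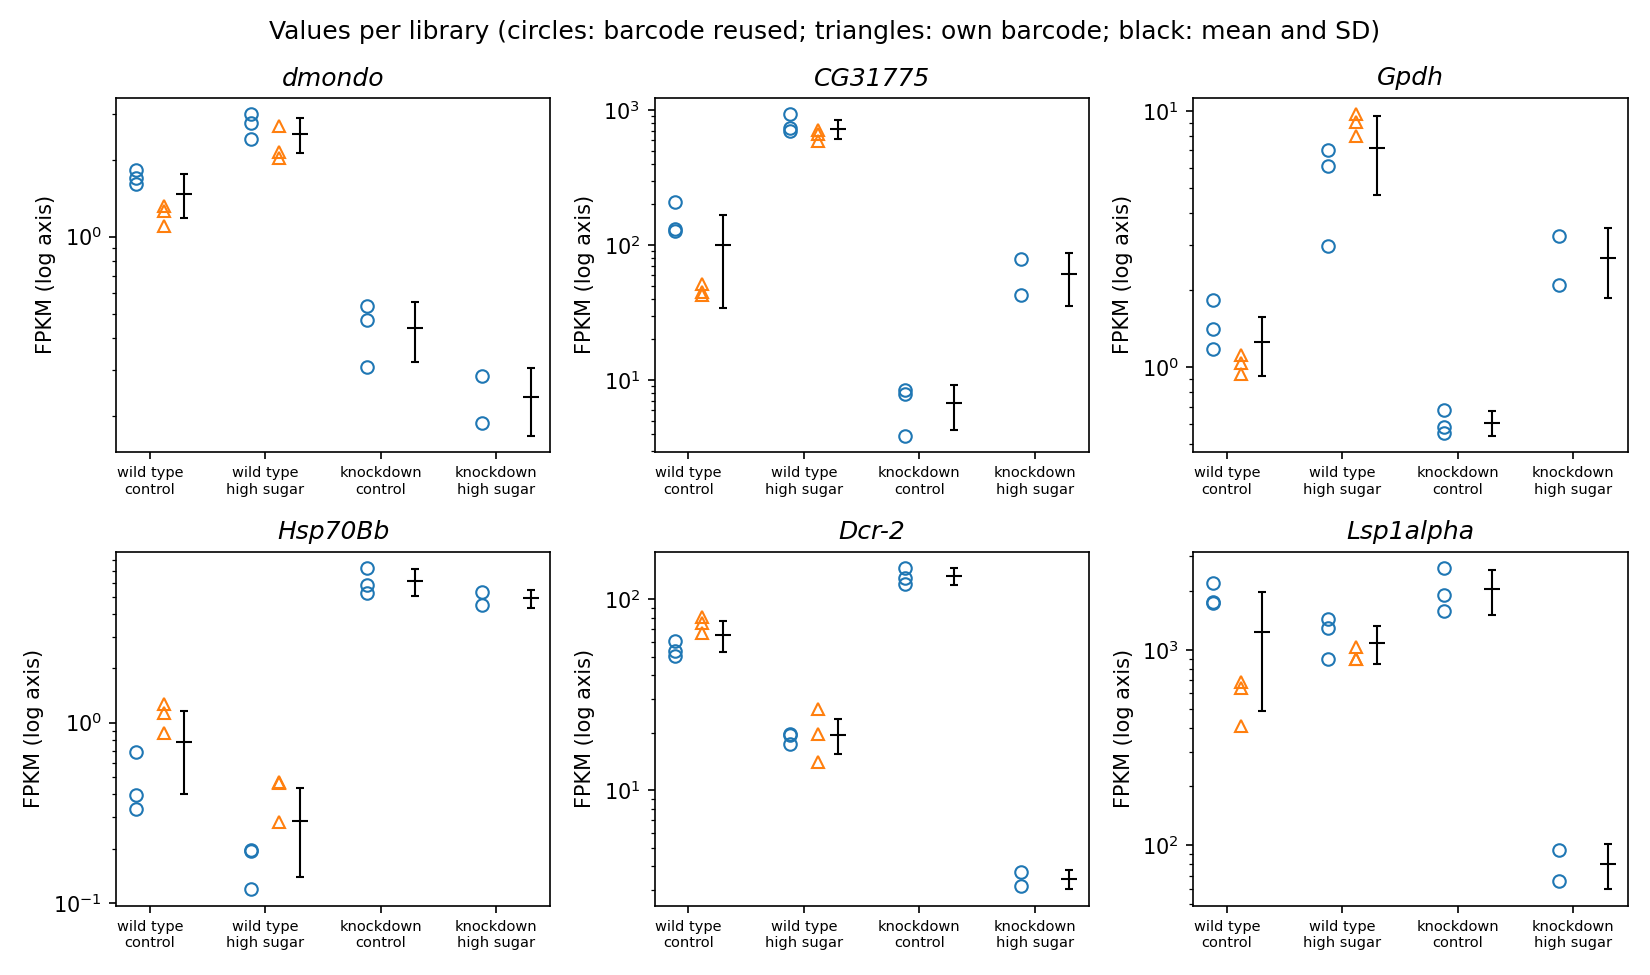
FPKM of 6 genes in each of the 17 libraries, on log axes, with circles for libraries of the shared-barcode set, triangles for those of the own-barcode set, and a black bar for each group's mean and SD. The knockdown libraries lie below all wild-type libraries for dmondo and above them for Hsp70Bb, and Lsp1alpha averages 80.3 FPKM in the 2 knockdown libraries on high sugar against 2037 in the 3 on the control diet.

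The first comparison asks what a high-sugar diet did to the wild-type fat body. Gpdh (Gpdh1), which makes the glycerol backbone of triglycerides, went from 1.25 ± 0.325 to 7.15 ± 2.43 FPKM (SD, n = 6 each), a log2 change of 1.80 ± 0.19 (SE, limma adjusted p = 3.3e-05). The fatty acid desaturase desat1 rose by 1.53 ± 0.30, acetyl-CoA synthetase (AcCoAS) by 1.102 ± 0.15 and malic enzyme (Men) by 0.77 ± 0.19. Also up were fatty acid synthase (CG3523, FASN1) by 0.65 ± 0.19, the diacylglycerol acyltransferase midway (mdy) by 0.55 ± 0.13 and the lipid droplet coat protein Lsd-1 by 1.04 ± 0.19. Of 6 measured fatty acid synthesis genes 4 rose and none fell (4 adjusted over the list alone), and of 6 genes of triglyceride synthesis and droplet coats 4 rose and none fell (5 adjusted over the list alone). Camera with a preset correlation of 0.01 placed both lists above other genes (adjusted p = 0.016 and 0.0025). With an estimated correlation both had an adjusted p of 0.34. Within the shared-barcode set 1 gene of each list was called higher (medians 0.39 and 0.15), against 4 and 5 within the own-barcode set (1.03 and 0.85).

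Of 12 measured glycolysis genes 6 rose with sugar in wild type (6 adjusted over the list alone), with phosphoglucose isomerase (Pgi) up by 0.88 ± 0.21, enolase (Eno) by 0.75 ± 0.19, Aldolase by 0.71 ± 0.15 and pyruvate kinase (PyK) by 0.49 ± 0.08. In gluconeogenesis 3 of 4 rose (4 adjusted over the list alone): phosphoenolpyruvate carboxykinase (Pepck) by 1.08 ± 0.18, pyruvate carboxylase (CG1516) by 0.99 ± 0.22 and the second carboxykinase CG10924 by 0.73 ± 0.18. In the trehalose, glycogen and sugar transport list 5 of 8 rose (6 adjusted over the list alone), among them trehalose-6-phosphate synthase (Tps1) by 0.83 ± 0.21 and glycogen phosphorylase (GlyP) by 0.52 ± 0.11. In the pentose phosphate and NADPH list 3 of 6 rose (3 adjusted over the list alone), including Pgd by 0.55 ± 0.13. Of 18 genes of lipolysis and fatty acid oxidation 4 rose (4 adjusted over the list alone), including the adipokinetic hormone receptor (GRHR, AkhR) by 0.88 ± 0.15. No measured member of these 5 lists fell. Camera's preset adjusted p values were 0.00079, 0.0037, 0.0037, 0.033 and 0.0025 in this order. With an estimated correlation the adjusted p values were 0.34, 0.34, 0.34, 0.45 and 0.45. Within the shared-barcode set 1, 0, 0, 0 and 0 genes of these lists were called higher (medians 0.15, 0.42, 0.06, 0.08 and -0.02), against 11, 4, 7, 4 and 14 within the own-barcode set (0.83, 1.38, 0.88, 0.64 and 0.59). In the Mondo-Mlx network 2 of 5 rose (2 adjusted over the list alone, camera adjusted p = 0.077): dmondo and the sugar-responsive transcription factor sugarbabe, by 0.88 ± 0.18.

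Among genes named by the rule, the largest wild-type rises were those of CG31775 and CG42586, overlapping genes whose reads cannot be told apart in these values and which are therefore uncertain as separate genes. CG31775 went from 101 ± 66.5 to 724 ± 115 FPKM (SD, n = 6 each), a log2 change of 3.09 ± 0.27 (limma adjusted p = 2.9e-06), and CG42586 changed by 3.08 ± 0.27. CG3348 rose by 2.82 ± 0.20, the cytochrome P450 Cyp4d1 by 1.98 ± 0.25, CG5773 by 1.65 ± 0.23, CG8157 by 1.13 ± 0.20 and CG14375, which encodes the nutrient-dependent peptide hormone CCHa2, by 1.05 ± 0.18. The endoplasmic reticulum chaperones Gp93, Hsc70-3 (BiP) and Crc (calreticulin) rose by 1.25 ± 0.17, 0.85 ± 0.12 and 1.03 ± 0.17. MtnA, a metal-binding metallothionein, had the largest fall among genes named by the rule, from 38.0 ± 10.8 to 5.33 ± 4.41 FPKM (SD, n = 6 each; log2 change -2.91 ± 0.31). CG31698 fell by 2.44 ± 0.66, the sulfiredoxin CG6762 by 1.91 ± 0.13, Kaz1-ORFB by 1.36 ± 0.20 and the cell adhesion gene Ama by 1.23 ± 0.22. CG6870 fell by 1.16 ± 0.13, CG10962 by 1.08 ± 0.16, Cyp6d5 by 1.04 ± 0.16 and glycine N-methyltransferase (CG6188) by 0.99 ± 0.31. Dcr-2, which the wild-type larvae also carry as a transgene, fell by 1.68 ± 0.14, from 64.7 ± 12.05 to 19.5 ± 4.07 FPKM (SD, n = 6 each). The other measured member of the transgene list, Cg25C, differed by 0.35 ± 0.20 (adjusted p = 0.25).

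Other lists moved in parts. Among 21 genes of oxidative stress and detoxification 3 rose and 5 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.55). Cyp4e3 was up by 1.84 ± 0.28 and Cyp4p1 by 1.28 ± 0.15, and the glutathione transferase GstD3 was down, at -1.27 ± 0.14. Among 18 heat shock and endoplasmic reticulum stress genes 5 rose and 3 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.94). Of 23 immune genes 1 rose and none fell (0 adjusted over the list alone), with a preset camera adjusted p of 0.016 in the upward direction and an adjusted p of 0.67 with an estimated correlation. None was called higher and 1 lower in the shared-barcode set (median 0.08), against 9 and 0 in the own-barcode set (1.49), with a camera adjusted p of 0.026 for the difference (0.68 with an estimated correlation). Of 83 cytosolic ribosomal protein genes 5 rose (1 adjusted over the list alone), RpL5 by 0.48 ± 0.10, with a preset adjusted p of 0.034, an adjusted p of 0.75 with an estimated correlation, and 9 called and 0.0029 with the length trend removed. The ribosomal median was -0.14 with 0 of 83 called in the shared-barcode set and 0.35 with 15 called higher in the own-barcode set, and the list's direction reversed with wild-type replicates 4 to 6 left out (adjusted p = 0.15). In the storage protein list 2 of 12 rose (2 adjusted over the list alone, camera adjusted p = 0.28), among them the larval serum protein Lsp1gamma by 1.61 ± 0.45. The direction of that list turned between the sets: 0 were higher and 1 lower in the shared-barcode set (median -0.04) and 6 and 0 in the own-barcode set (0.41), with a camera adjusted p of 0.023 for the difference (0.27 with an estimated correlation). The polyol list had 1 fall in 4, sorbitol dehydrogenase (Sodh-1) at -1.11 ± 0.14 (1 adjusted over the list alone, camera adjusted p = 0.28). The ecdysone and stage list had 1 fall in 8, Eip55E at -0.93 ± 0.16 (1 adjusted over the list alone, camera adjusted p = 0.077). The insulin and secreted signal list had 1 rise, daw at 0.44 ± 0.14, and 1 fall, CG15917 at -0.71 ± 0.20, in 10 (1 and 1 adjusted over the list alone, camera adjusted p = 0.95). The proteasome list had 1 rise in 33 (0 adjusted over the list alone, camera adjusted p = 0.069) and the 2 measured maltases had no call (1 fall adjusted over the list alone). In the oxidative stress list 2 were higher and 4 lower in the shared-barcode set and 5 and 1 in the own-barcode set (camera adjusted p = 0.30 for the difference), and in the heat shock list 2 and 0 against 5 and 5 (0.57). The median, the mean and the camera direction differed in sign for the polyol, insulin, oxidative stress and heat shock lists.

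Among markers of other tissues in wild type, hemocyte markers had 3 falls in 7 (1 rise and 4 falls adjusted over the list alone), including the prophenoloxidases CG8193 at -1.23 ± 0.29 and proPO-A1 at -1.104 ± 0.28. In the shared-barcode set 0 hemocyte genes were called, and in the own-barcode set 1 was higher and 4 lower, with a camera adjusted p of 0.018 for the difference (0.27 with an estimated correlation). The hemocyte sum of 1 shared-barcode library on the control diet, 354 FPKM, stood apart from the other 5 of its group. Muscle markers had 1 fall in 5 (1 adjusted over the list alone), Act57B at -0.64 ± 0.15, and Malpighian tubule and trachea markers 1 in 3 (1 adjusted over the list alone), Uro at -1.46 ± 0.36. The preset adjusted p values were 0.033, 0.033 and 0.049. With an estimated correlation the adjusted p values were 0.34, 0.34 and 0.45. The Malpighian tubule and trachea median was 0.32 with 0 of 3 called in the shared-barcode set and -1.40 with 3 called lower in the own-barcode set, and the list's direction reversed with wild-type replicates 4 to 6 left out (adjusted p = 0.25). Removal of the length trend put that list at 0.077. None of 17 midgut proteases, 11 salivary glue genes, 4 cuticle genes or 1 neuronal marker was called (0, 0, 3 falls and 0 adjusted over the list alone; camera adjusted p = 0.068, 0.31 and 0.055 for the first 3), and no gonad marker passed the filter. Within the shared-barcode and own-barcode sets 0 and 2 midgut proteases (medians 0.16 and -1.02), 0 and 7 glue genes (0.75 and -2.76) and 3 and 0 cuticle genes (-1.37 and 0) were called lower, with camera adjusted p values of 6.1e-05, 1.4e-06 and 0.12 for the difference (0.42, 0.27 and 0.54 with an estimated correlation). Summed glue values differed by barcode set: they averaged 3343 FPKM on the control diet and 5539 on high sugar in the shared-barcode wild-type libraries (n = 3 each), against 455 and 13.3 in the own-barcode ones (n = 3 each).

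In all, 370 of 2383 tested genes changed with sugar in wild type, 225 up and 145 down. Within the shared-barcode set 152 genes were called (40 up, 112 down) and within the own-barcode set 797 (509 up, 288 down), in a fit with a mean for each group and set. The diet effects of the 2 sets had a Pearson r of 0.113 across genes, which are not independent replicates. A direct test of the difference between sets called 473 genes. By that test, taken list by list after these values were seen, 5 of 12 glycolysis, 3 of 6 triglyceride, 7 of 18 lipolysis and oxidation, 2 of 4 gluconeogenesis, 2 of 6 pentose phosphate, 6 of 8 trehalose and 1 of 6 fatty acid synthesis genes had a higher sugar effect in the own-barcode set, and none of them a lower one. Preset camera adjusted p values for the difference were 0.0027, 0.018, 0.00027, 0.037, 0.037, 0.0053 and 0.48 in this order, and with an estimated correlation they ran from 0.27 to 0.78. With wild-type replicates 4 to 6 left out, 78 genes were called (21 up, 57 down) and no metabolic list was called. The count was 142 with a minimum mean of 5, 167 without the set term and 563 in the fit with a mean for each group and set.

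**Figure D2:**
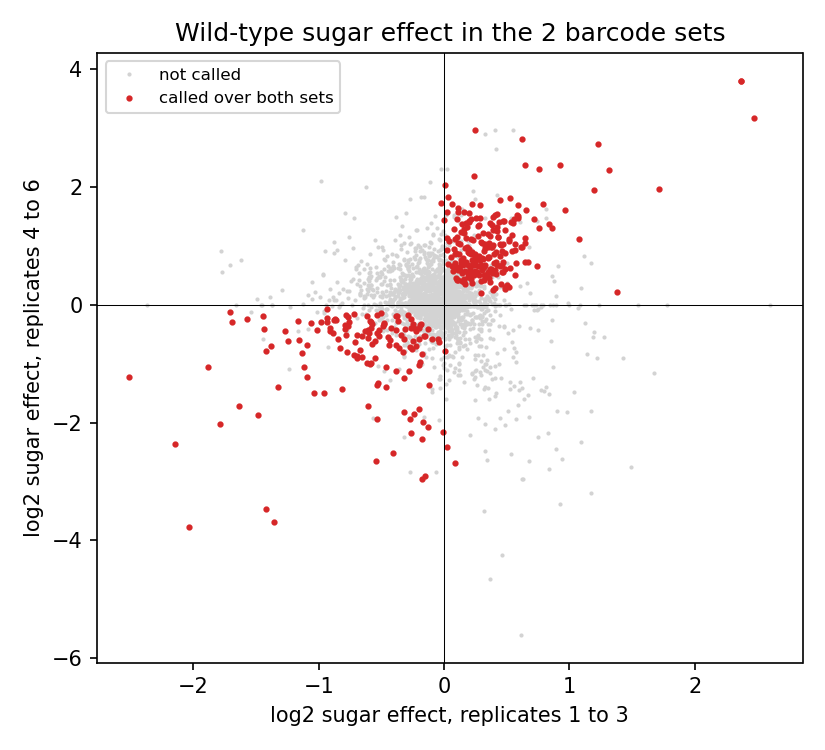
Log2 change with high sugar in wild type for each of the 2383 tested genes, in replicates 1 to 3 (x axis, shared-barcode set) and in replicates 4 to 6 (y axis, own-barcode set), with the 370 genes called over both sets in red. Across genes the 2 effects had a Pearson r of 0.113.

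The second comparison asks what the knockdown did on the control diet. No group carried a control construct, so here and on high sugar effects of the construct or line cannot be told apart from those of lower dmondo. Among genes named by the rule CG32407 had the largest rise, from 0.675 ± 0.539 FPKM in wild type (SD, n = 6) to 34.1 ± 3.40 in the knockdown (SD, n = 3), a log2 change of 4.01 ± 0.15 (SE, limma adjusted p = 1.3e-10). CG31775 showed the largest fall among them, from 101 ± 66.5 (SD, n = 6) to 6.74 ± 2.50 FPKM (SD, n = 3; log2 change -4.00 ± 0.35, adjusted p = 3.4e-06), with its overlapping neighbour CG42586 at -3.97 ± 0.35. CG5773, another gene that rose with sugar in wild type, fell by 1.79 ± 0.30. In the Mondo-Mlx network 2 of 5 members fell (2 adjusted over the list alone): dmondo, and the transcription factor cabut (cbt) by 0.71 ± 0.18, while sugarbabe was at -0.56 ± 0.24 (adjusted p = 0.21). The list had a preset camera adjusted p of 0.031 and an adjusted p of 0.52 with an estimated correlation. It includes the knockdown target dmondo itself, so these p values do not speak for the rest of the network alone.

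Stress and detoxification genes went in both directions in the knockdown on the control diet. Of 21 measured, 3 rose and 3 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.93). Cyp4e3 was up by 3.61 ± 0.38 and GstD3 by 2.03 ± 0.19. GstD1 fell by 1.54 ± 0.20 and Cyp4e2 by 0.81 ± 0.17. The peroxiredoxin Prx2540-1 rose by 2.28 ± 0.26. Of 18 heat shock and endoplasmic reticulum genes 3 rose and none fell (3 adjusted over the list alone, camera adjusted p = 0.19). These were Hsp70Bb (2.21 ± 0.12), Hsp70Ba (1.93 ± 0.12) and Hsp70Bc (1.81 ± 0.11), near-identical copies among which reads cannot be assigned with certainty. Hsp70Bb went from 0.782 ± 0.383 (SD, n = 6) to 6.11 ± 1.02 FPKM (SD, n = 3). None of the 8 other inducible heat shock genes and cochaperones examined, chosen after the Hsp70B values were seen, was called by limma, and at an unadjusted p under 0.05 there was 1, lower.

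In metabolism on the control diet, the triglyceride lipase brummer (bmm) rose by 1.0999 ± 0.15, Pepck by 1.43 ± 0.24 and isocitrate dehydrogenase (Idh) by 1.36 ± 0.23 in the knockdown, and PyK fell by 0.44 ± 0.10. They were the only calls in their lists: 1 up in 18 for lipolysis and fatty acid oxidation (1 adjusted over the list alone) and 1 up in 4 for gluconeogenesis (2 adjusted over the list alone). There was 1 up in 6 for the pentose phosphate and NADPH list (1 adjusted over the list alone) and 1 down in 12 for glycolysis (2 adjusted over the list alone). Camera adjusted p values were 0.93, 0.091, 0.93 and 0.091, and gluconeogenesis had 2 genes up and 0.0499 with the length trend removed. With an estimated correlation, used only with the trend left in, gluconeogenesis had a camera adjusted p of 0.97. None of the 6 fatty acid synthesis genes and none of the 6 triglyceride and droplet coat genes was called on this diet (0 and 0 adjusted over the list alone, camera adjusted p = 0.93 for each). Thor, the translation inhibitor 4E-BP, fell by 0.98 ± 0.19, the sole call in the insulin list (1 of 10, 1 adjusted over the list alone, camera adjusted p = 0.66). Further rises were those of CG4716 (3.09 ± 0.37), CG6459 (2.97 ± 0.45), the sugar transporter gene CG10960 (2.42 ± 0.24), a predicted gene without a CG number (2.11 ± 0.38), CG18473 (2.08 ± 0.24), the inositol oxygenase CG6910 (1.63 ± 0.30) and Eip55E (1.03 ± 0.22). Further falls were those of CG5697 (-2.29 ± 0.52), alcohol dehydrogenase Adh (-2.08 ± 0.40), glutamine synthetase Gs1 (-1.60 ± 0.27), CG34436 (-1.47 ± 0.23) and CG8369 (-1.33 ± 0.22). Dcr-2 was higher in the knockdown by 1.15 ± 0.18, at 132 ± 13.2 FPKM (SD, n = 3).

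The immune list as a whole lay above other genes in the knockdown on the control diet, with a preset camera adjusted p of 0.0083. With an estimated correlation the adjusted p was 0.97, and 0 of 23 members were called (0 adjusted over the list alone). Its members with the smallest p included drosocin (Dro) at 2.93 ± 0.84 (adjusted p = 0.056) and attacin A (AttA) at 2.65 ± 0.81 (adjusted p = 0.073). The larval cuticle genes Lcp3 (-1.32 ± 0.31) and Lcp4 (-1.30 ± 0.35) fell, 2 of 4 in the cuticle list (3 adjusted over the list alone), with a preset adjusted p of 0.0098 and an adjusted p of 0.97 with an estimated correlation. The cuticle sum was 0.098 FPKM in own-barcode wild-type libraries (n = 3) and 82.2 in shared-barcode ones (n = 3) on the control diet, and without the set term Lcp4 was at 0.76 and Lcp3 at 0.070. The median, the mean and the camera direction differed in sign for the fatty acid synthesis, pentose phosphate, trehalose, oxidative stress, heat shock and hemocyte lists.

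In all, 134 genes differed between knockdown and wild type on the control diet, 72 higher and 62 lower, and with the wild-type libraries of the own-barcode set left out 135 did (53 higher, 82 lower), 89 of which were among the 134. The count was 79 without knockdown replicate 3 on the control diet, 239 with a mean for each group and set (83 higher, 156 lower, 122 of them among the 134), 242 without a filter and 70 with a minimum mean of 5.

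The third comparison asks what the knockdown did on high sugar, where each knockdown mean rests on 2 libraries. Of 12 measured genes in the list of storage and secreted fat body proteins 8 fell and none rose (8 adjusted over the list alone). Not every member is itself secreted, Mtp among the 8 being an exception. The storage protein Lsp1alpha dropped from 1078 ± 237 FPKM in wild type (SD, n = 6) to 80.3 ± 20.8 in the knockdown (SD, n = 2). The fitted log2 change, with the set term, was -4.25 ± 0.38 (SE, limma adjusted p = 5.2e-07). Lsp1gamma fell by 3.82 ± 0.67, Lsp1beta by 2.59 ± 0.41, the lipid carrier apolipophorin (Rfabg) by 3.74 ± 0.29 and the ferritin light chain Fer2LCH by 1.22 ± 0.14, while Lsp2 was at -0.59 ± 0.32 (adjusted p = 0.13). The list had a preset camera adjusted p of 0.012, an adjusted p of 0.73 with an estimated correlation, and 0.055 once each library's trend with transcript length was removed. Its median was -1.35 before that removal and -1.08 after it, with 8 members called lower each time.

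Of 6 triglyceride and droplet coat genes 5 fell in the high-sugar knockdown (5 adjusted over the list alone), among them the droplet coat proteins Lsd-1 by 1.56 ± 0.28 and Lsd-2 by 1.68 ± 0.21. The list as a whole had a camera adjusted p of 0.064, and 0.21 with the length trend removed. Brummer fell by 1.23 ± 0.17, in contrast to its rise on the control diet, and 4 of 18 lipolysis and oxidation genes rose and 6 fell (4 and 6 adjusted over the list alone, camera adjusted p = 0.98). Once that trend was removed 6 of them were higher and 1 lower, and the median turned from -0.12 to 0.25 (adjusted p = 0.30). In fatty acid synthesis 1 rose, Men by 1.39 ± 0.28, and 1 fell, CG3523 by 1.33 ± 0.28, of 6 (1 and 1 adjusted over the list alone, camera adjusted p = 0.80). CG3523 was at -0.07 (adjusted p = 0.85) with the length trend removed, 2 genes of its list were higher and 0 lower, and the median turned from -0.31 to 0.41 (adjusted p = 0.26). In FPKM, CG3523 averaged 0.764 ± 0.295 in the knockdown (SD, n = 2) and 3.22 ± 0.872 in wild type (SD, n = 6). The insulin-like peptide Ilp6 fell by 2.73 ± 0.19, from 15.6 ± 4.01 (SD, n = 6) to 1.93 ± 0.107 FPKM (SD, n = 2), and Thor by 3.49 ± 0.21. In that list 1 of 10 rose and 6 fell (1 and 6 adjusted over the list alone, camera adjusted p = 0.080). Aldolase fell by 1.58 ± 0.22 and GlyP by 0.94 ± 0.16 (-0.28 and no longer called with the length trend removed, adjusted p = 0.13), Idh rose by 1.73 ± 0.26 and the maltase CG30360 by 1.37 ± 0.24. Of the Mondo-Mlx network 3 of 5 fell (3 adjusted over the list alone, camera adjusted p = 0.34): dmondo, cbt by 1.22 ± 0.20 and sugarbabe by 0.94 ± 0.27.

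Of 83 ribosomal protein genes 50 rose and 11 fell in the high-sugar knockdown (53 and 12 adjusted over the list alone), with RpL36 up by 1.52 ± 0.21, RpL38 up by 1.29 ± 0.17, RpL35 at -1.46 ± 0.17 and RpL22 at -1.73 ± 0.24. Of 33 proteasome genes 18 rose and 3 fell (18 and 3 adjusted over the list alone), with Prosbeta5 at 2.12 ± 0.19 and Prosalpha5 at 1.63 ± 0.19. Of 18 heat shock and endoplasmic reticulum genes 10 rose and 2 fell (11 and 2 adjusted over the list alone), among them Hsp70Bb (2.40 ± 0.14), Hsp70Ba (2.16 ± 0.14) and Hsp70Bc (1.94 ± 0.12), the same near-identical copies. Preset camera adjusted p values were 0.00016, 0.0033 and 0.0040. With an estimated correlation all 3 lists had an adjusted p of 0.73. With the length trend removed the ribosomal counts were 33 higher and 16 lower and the list's adjusted p was 0.26, while the proteasome and heat shock lists were at 0.0022 and 0.00093. Among detoxification genes 10 of 21 rose and 5 fell (10 and 5 adjusted over the list alone, camera adjusted p = 0.34), with Cyp4e3 up by 2.97 ± 0.43 and GstD3 by 2.47 ± 0.21. Of the 23 immune genes 4 fell and none rose (3 adjusted over the list alone, camera adjusted p = 0.86), including drosomycin (Drs) by 2.70 ± 0.44 and the NF-kB factor Relish (Rel) by 1.44 ± 0.29.

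Of 17 genes of the midgut protease list, which include LysD and CG5932, 15 rose and none fell in the same comparison (16 adjusted over the list alone). The list had a preset camera adjusted p of 0.00017 and an adjusted p of 0.73 with an estimated correlation. Once the length trend was removed 9 were called higher (preset adjusted p = 0.0015). Jon25Biii went from 0.350 ± 0.109 (SD, n = 6) to 23.0 ± 4.71 FPKM (SD, n = 2; log2 change 4.35 ± 0.50). Jon99Ciii rose by 3.80 ± 0.50, Jon99Cii by 3.56 ± 0.47 and Jon99Fi by 2.41 ± 0.32. Jon99Cii and Jon99Ciii are near-identical, so reads cannot be assigned between them with certainty. The summed midgut values averaged 414 FPKM in the high-sugar knockdown (n = 2), 97.6 in shared-barcode (n = 3) and 4.15 in own-barcode wild type on high sugar (n = 3), with a log2 change from shared-barcode wild type of 2.42 ± 1.15 (SE, t test in a linear model, adjusted p = 0.088). Both measured maltases rose (2 adjusted over the list alone). The glue gene Sgs1 fell by 3.32 ± 0.40, with 1 glue gene of 11 up and 1 down (0 and 1 adjusted over the list alone). The muscle gene Mlc2 rose by 1.65 ± 0.27, with 2 of 5 up (2 adjusted over the list alone). Lcp4 rose by 2.27 ± 0.40, with 2 of 4 cuticle genes up (2 adjusted over the list alone). The hemocyte marker CG2736 fell by 2.41 ± 0.26, with 2 of 7 up and 3 down (2 and 3 adjusted over the list alone), and 2 up and 1 down with the length trend removed. The Malpighian tubule and trachea list had 0 of 3 called by limma (0 adjusted over the list alone). Camera adjusted p values for these 5 lists were 0.88, 0.37, 0.25, 0.91 and 0.98. Their sums changed from shared-barcode wild type by 0.78 ± 1.03, 0.80 ± 0.20, 1.93 ± 0.43, 2.15 ± 0.64 and -0.40 ± 0.35 (SE, adjusted p = 0.46, 0.0071, 0.0054, 0.013 and 0.34). The hemocyte sum thus rose, from 69.0 to 329 FPKM, of which Nplp2, chosen after its value was seen, made up 30.4 and 316. Other large rises were CG10814 (4.43 ± 0.27), CG7916 (4.34 ± 0.90), CG14963 (3.77 ± 0.70), CG13335 (3.56 ± 0.60), the acyl-CoA binding protein gene CG15829 (3.56 ± 0.67), CG8997 (3.42 ± 0.86), CG31789 (3.36 ± 0.96) and Ag5r2 (3.36 ± 0.47). Other large falls were CG31775 (-4.09 ± 0.40), CG42586 (-4.09 ± 0.40), l(1)G0320 (-3.93 ± 0.74), the serpin CG6687 (-3.70 ± 0.46), CG7997 (-3.54 ± 0.26) and Adh (-3.49 ± 0.45). Dcr-2 was lower by 2.07 ± 0.21, the reverse of the control diet, at 3.43 ± 0.407 FPKM (SD, n = 2), and by 1.03 (adjusted p = 8.4e-05) with the length trend removed.

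In all, 1443 genes differed between knockdown and wild type on high sugar, 648 higher and 795 lower, and 1515 (723 higher, 792 lower) with the own-barcode wild-type libraries left out. The median, the mean and the camera direction differed in sign for the lipolysis, gluconeogenesis and hemocyte lists. The changes followed transcript length, with a Spearman rho of -0.43 across 2298 genes and a median log2 change of 0.68 in the 144 genes with the shortest transcripts and -0.91 in the 69 with the longest. With each library's length trend removed 1264 genes were called, 1012 of them also called before in the same direction.

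**Figure D3:**
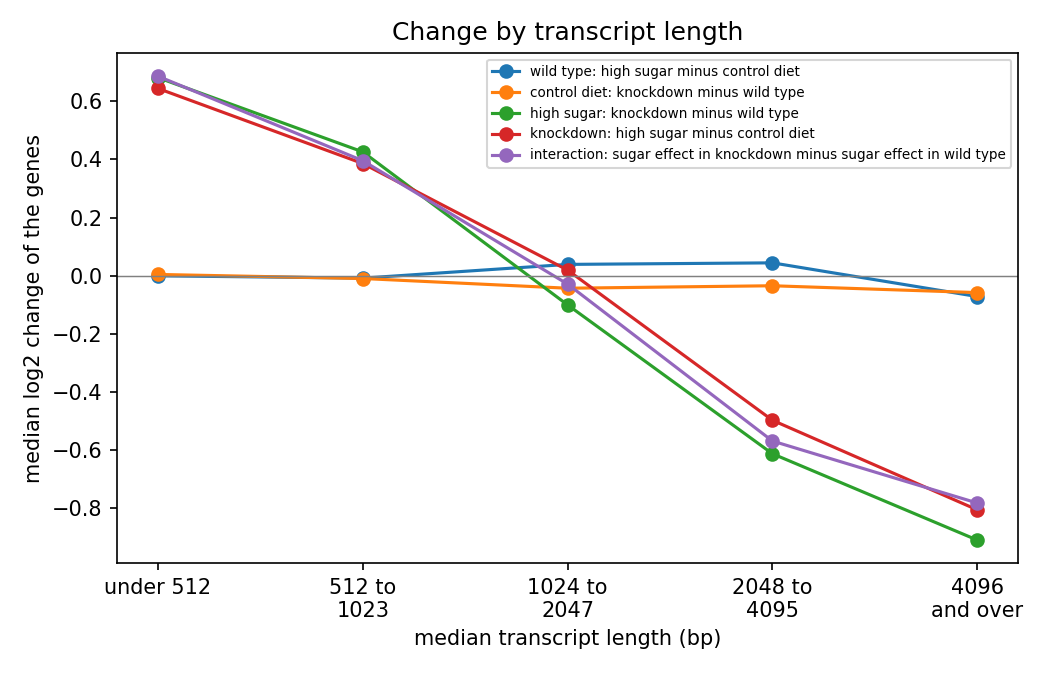
Median log2 change of the tested genes in each of 5 ranges of median transcript length (x axis, bp), 1 line per comparison. The 3 comparisons that involve the high-sugar knockdown libraries run from between 0.64 and 0.69 in the shortest range to between -0.78 and -0.91 in the longest, and the other 2 lie between -0.07 and 0.04.

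The fourth comparison asks what sugar did in the knockdown itself, in 2 high-sugar and 3 control libraries of the shared-barcode set. Several sugar-responsive genes rose as in wild type: CG31775 by 2.99 ± 0.42 (SE, limma adjusted p = 2.8e-05), CG3348 by 2.91 ± 0.32 and CG5773 by 2.22 ± 0.36, all 3 chosen after their values were seen. In fat synthesis desat1 rose by 1.43 ± 0.47, AcCoAS by 0.91 ± 0.23, Men by 1.77 ± 0.30 and Gpdh by 1.17 ± 0.31. Of 6 fatty acid synthesis genes 3 were up and 1 down (3 and 1 adjusted over the list alone, camera adjusted p = 0.69), but 6 up and 0 down with the length trend removed, when the median went from 0.41 to 1.31 (adjusted p = 0.034). These 6 rises are relative to genes of like length. Mean FPKM was lower on high sugar for HLH106 (SREBP, 1.60 to 0.90), ATPCL (1.28 to 0.80) and CG3523 (0.90 to 0.76). With an estimated correlation, used only with the trend left in, the list's camera adjusted p was 0.98. Of 6 triglyceride genes 1 was up and 2 were down (1 and 3 adjusted over the list alone, camera adjusted p = 0.68). Pentose phosphate genes rose in 3 of 6 (3 adjusted over the list alone, camera adjusted p = 0.13), with transaldolase (Tal) at 2.11 ± 0.29 and Pgd at 1.42 ± 0.20. The target dmondo was at -0.22 ± 0.11 (adjusted p = 0.11), and 0.60 (adjusted p = 0.00077) with the length trend removed. Its FPKM did not rise, at 0.310 to 0.535 in the 3 control-diet libraries and 0.187 to 0.286 in the 2 on high sugar. The 0.60 is thus a change relative to genes of like length. The partner bigmax rose by 0.55 ± 0.15 (adjusted p = 0.0063, and 0.090 with the trend removed).

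Brummer fell by 2.20 ± 0.18 with sugar in the knockdown, from 6.85 ± 1.32 (SD, n = 3) to 0.693 ± 0.183 FPKM (SD, n = 2). Thor fell by 2.61 ± 0.22, Ilp6 by 2.68 ± 0.21, trehalase (Treh) by 0.81 ± 0.12 and phosphoglucomutase (Pgm) by 1.097 ± 0.23. Treh was no longer called with the length trend removed (adjusted p = 0.11). Lsp1alpha fell by 4.64 ± 0.40 and Rfabg by 3.72 ± 0.30. Of 12 genes in the list of storage and secreted fat body proteins 8 were down and 1 up (8 and 1 adjusted over the list alone, preset adjusted p = 0.049, adjusted p = 0.80 with an estimated correlation, and 0.083 with the length trend removed). Ribosomal protein genes rose in 58 of 83 and fell in 10 (58 and 12 adjusted over the list alone), RpL8 at 2.40 ± 0.25 and RpL35 at -1.60 ± 0.18. Proteasome genes rose in 21 of 33 and fell in 3 (21 and 3 adjusted over the list alone), Prosbeta5 at 2.16 ± 0.20. Midgut proteases rose in 7 of 17 (7 adjusted over the list alone), Jon25Biii at 3.85 ± 0.53, Jon66Ci at 3.43 ± 0.54 and CG18180, which is outside the list, at 3.35 ± 0.45. Their preset adjusted p values were 2.7e-06, 0.0021 and 0.014. Each had an adjusted p of 0.80 with an estimated correlation. Heat shock and endoplasmic reticulum genes rose in 11 of 18 and fell in 1 (11 and 1 adjusted over the list alone, camera adjusted p = 0.087, and 0.0055 with the length trend removed). With an estimated correlation, which was used only with the trend left in, this list was not called. The small heat shock proteins Hsp22 and Hsp26 were at 3.38 ± 0.41 and 3.20 ± 0.57 and the stress factor Xbp1 at 1.78 ± 0.20. GstD1 rose by 2.49 ± 0.23 and superoxide dismutase (Sod) by 1.72 ± 0.23.

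Among genes named by the rule the largest change with sugar in the knockdown was the fall of Dcr-2, from 132 ± 13.2 (SD, n = 3) to 3.43 ± 0.407 FPKM (SD, n = 2; log2 change -4.90 ± 0.22). CG18563 (-3.72 ± 0.25), Sgs1 (-3.57 ± 0.42), the pteridine synthesis gene purple (pr, -3.48 ± 0.38), CG14852 (-3.41 ± 0.46), noncoding_12767 (-3.39 ± 1.03), CG7997 (-3.35 ± 0.27) and Sgs3 (-3.28 ± 1.36) also fell. Of 11 glue genes 2 rose and 4 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.93), with a median of 0.96, and the glue sum averaged 3934 FPKM on the control diet (n = 3) and 8962 on high sugar (n = 2). CG13947 (4.56 ± 0.73), CG14265 (4.24 ± 0.52), a predicted gene without a CG number (3.77 ± 0.36), Ag5r2 (3.66 ± 0.49), the cold-induced gene Frost (Fst, 3.65 ± 0.63), CG10814 (3.48 ± 0.29) and Lcp3 (2.89 ± 0.37) rose. In all, 1436 genes changed, 696 up and 740 down, with a Spearman rho of -0.36 against transcript length. With the length trend removed 1330 were called, 1111 of them called before in the same direction. The median, the mean and the camera direction differed in sign for the Mondo-Mlx, immune, oxidative stress and glue lists.

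The fifth comparison tests the difference between the sugar effects in knockdown and wild type. The knockdown effect rests on the shared-barcode set alone, while the wild-type effect is averaged over both sets. Since the wild-type effect differed between the sets for 473 genes, part of an interaction can come from the own-barcode libraries. Among blood and storage proteins the interaction was -4.81 ± 0.84 for Lsp1gamma, -4.68 ± 0.47 for Lsp1alpha and -3.84 ± 0.36 for Rfabg (log2, SE, limma adjusted p = 0.00030, 3.6e-06 and 2.7e-06). In that list 8 of 12 members were lower and none higher (8 adjusted over the list alone). Immune genes with a lower sugar response in the knockdown included IM3 (-4.37 ± 1.04) and Drs (-3.50 ± 0.55), with 4 of 23 lower in all (3 adjusted over the list alone, camera adjusted p = 0.56), and the thioester protein TepII (-3.40 ± 0.38), which is outside the list. Brummer (-2.33 ± 0.21), Lsd-2 (-1.55 ± 0.26), Lsd-1 (-1.35 ± 0.35), Thor (-2.51 ± 0.26), Ilp6 (-2.42 ± 0.24) and Treh (-0.98 ± 0.14) were lower as well, Treh with an adjusted p of 0.058 once the length trend was removed. The dmondo interaction of -0.73 ± 0.13 (adjusted p = 0.00045) became 0.12 (adjusted p = 0.51) with the length trend removed, and bigmax was at 0.41 ± 0.18 (adjusted p = 0.076). The dmondo mean rose with sugar in wild type, from 1.47 to 2.51 FPKM, and did not in the knockdown, at 0.439 and 0.236.

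Among single genes, Hsp26 (3.60 ± 0.67), Hsp22 (3.26 ± 0.49), Lcp4 (3.57 ± 0.50), Prosbeta5 (2.02 ± 0.23), RpL8 (1.95 ± 0.29) and GstD1 (2.68 ± 0.28) had a more positive sugar response in the knockdown. Of 18 heat shock and endoplasmic reticulum genes 8 were higher and 2 lower (8 and 2 adjusted over the list alone, camera adjusted p = 0.063, and 0.0072 with the length trend removed). Of 4 cuticle genes 3 were higher and none lower (3 adjusted over the list alone, camera adjusted p = 0.052, and 0.10 with the length trend removed). Both lists had an adjusted p of 0.79 with an estimated correlation. RpL35 went the other way (-1.56 ± 0.22). Fst (4.07 ± 0.75), CG13335 (3.65 ± 0.74), CG16762 (3.61 ± 0.54), CG12310 (3.47 ± 1.15), the same predicted gene without a CG number (3.38 ± 0.42), CG14265 (3.35 ± 0.62), CG13311 (3.34 ± 0.65) and CG34296 (3.31 ± 1.31) were the other large positive ones. The other large negative ones were pr (-3.77 ± 0.45), Sgs1 (-3.74 ± 0.49), the cuticle gene Cpr49Ac (-3.37 ± 0.23), CG7997 (-3.32 ± 0.32) and Dcr-2 (-3.22 ± 0.26). Of 83 ribosomal protein genes 49 were higher and 9 lower (52 and 10 adjusted over the list alone). Of 33 proteasome genes 17 were higher and 4 lower (17 and 4 adjusted over the list alone) and of 17 midgut proteases 8 and 0 (7 and 0 adjusted over the list alone). Preset camera adjusted p values for these 3 lists and for the secreted proteins were 3.2e-05, 0.0048, 0.0022 and 0.016. With an estimated correlation the adjusted p values were 0.84, 0.79, 0.79 and 0.79. The midgut protease sum was highest in the high-sugar knockdown, and the length trend was present here too (Spearman rho -0.39). With that trend removed the ribosomal list had an adjusted p of 0.076 and the secreted list 0.053. In all, 1235 genes had an interaction, 561 positive and 674 negative. With the own-barcode wild-type libraries left out 1213 did (592 positive, 621 negative), 1000 of which were among the 1235. The count was 1085 with the length trend removed, 866 of them called before in the same direction. The median, the mean and the camera direction differed in sign for the lipolysis and hemocyte lists.

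Over the 370 genes called in wild type, the sugar effect in the knockdown regressed on that in wild type with a slope of 0.706 and a Pearson r of 0.494, across genes that are not independent replicates. Over all 2383 genes the slope was 0.508 and r 0.200. Of the 225 genes that rose in wild type 96 also rose in the knockdown, where 65.7 would be shared by independent lists, 46 fell and 109 had an interaction. Of the 145 that fell in wild type 79 also fell in the knockdown, against 45.0 for independent lists, 13 rose and 74 had an interaction. The wild-type effects are inflated because the genes were chosen on them. With genes chosen on wild-type replicates 4 to 6 and the wild-type effect measured in replicates 1 to 3, the slope was 0.986 and r 0.375. The knockdown effects on the 2 diets, which share no libraries but share the estimated set term, had an r of 0.159 across genes, with 32 genes higher on both diets (19.6 for independent lists) and 34 lower on both (20.7).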

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

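The tests of library scaling and of other splits of the libraries were fixed before their results were seen, and the tests of transcript length, ribosomal protein length matching, other tissue markers, midgut protease proportions, other heat shock genes and white were chosen only after the results were seen.

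Single libraries stood apart from the other 5 of their wild-type group in 17 of 336 groups of values tested (5.06%), where chance gives about 1 in 20, by the gap to the nearest library as a share of the group's range. On the control diet this share was 0.784 for CG1516, 0.753 for Jon25Biii, 0.647 for CG15829, 0.704 for l(1)G0320, 1 for CG13947, 0.694 for Jon66Ci, 0.641 for CG13311 and 0.807 for the hemocyte marker sum. On high sugar it was 0.843 for desat1, 0.644 for CG3523, 0.7098 for GstD1, 0.742 for Dro, 0.793 for CG10814, 0.640 for Rel, 0.729 for the fatty acid synthesis sum, 0.667 for the immune sum and 0.660 for the cuticle sum.

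The sugar effect differed between knockdown and wild type, by the interaction test, for 1235 genes. Among named genes it was more positive in the knockdown for Fst (4.07), CG13335 (3.65), CG16762 (3.61), Hsp26 (3.60), Lcp4 (3.57), CG12310 (3.47), a predicted gene without a CG number (3.38), CG14265 (3.35), CG13311 (3.34), CG34296 (3.31), Hsp22 (3.26), GstD1 (2.68), Prosbeta5 (2.02) and RpL8 (1.95). It was more negative for Lsp1gamma (-4.81), Lsp1alpha (-4.68), IM3 (-4.37), Rfabg (-3.84), pr (-3.77), Sgs1 (-3.74), Drs (-3.50), TepII (-3.40), Cpr49Ac (-3.37), CG7997 (-3.32), Dcr-2 (-3.22), Thor (-2.51), Ilp6 (-2.42), bmm (-2.33), RpL35 (-1.56), Lsd-2 (-1.55), Lsd-1 (-1.35), Treh (-0.98) and dmondo (-0.73). With the length trend removed dmondo was at 0.12 (adjusted p = 0.51), Treh at -0.35 (0.058) and CG34296 at 2.72 (0.10), none of them called. The diet effect in wild type differed between the 2 barcode sets for 473 genes.

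The first pattern weighed is the broad shift in the high-sugar knockdown, with lower secreted proteins and higher ribosomal protein and midgut protease genes. A trend with transcript length, as fitted here, is excluded as the whole account, since 72.9% of the called genes with a known length kept call and direction once it was removed. A bias that the fitted curve misses would remain, and the removal cannot exclude it. The ribosomal median of 0.73 lay above 99.5% of medians of length-matched lists. Those lists drew genes independently, while the ribosomal list had an estimated inter-gene correlation of 0.50, so the percentile overstates how far it stands apart. The ribosomal list's camera adjusted p became 0.26 after removal and 9 midgut proteases were called against 15 before, so length may account for part of both rises. A lower share of fat body RNA could also lower the secreted proteins, and would raise markers of other tissues alike if those tissues kept their proportions. They did not: 4 of 15 pairs of 6 marker list sums differed in their change from shared-barcode wild type. Of these pairs 3 were without the hemocyte sum, which is mostly 1 gene. Cuticle minus Malpighian tubule differed by 2.32 ± 0.55 (t test in a linear model, adjusted p = 0.011). This test replaced a comparison of 2 secreted proteins picked by their values. It cannot exclude a lower fat body share, since other tissues can enter the samples in unequal amounts. A lower share alone would lower the secreted list's members alike, yet the 12 ran from -4.25 ± 0.38 (Lsp1alpha) to 0.42 ± 0.21 (Fer1HCH). The 8 called falls ran from -4.25 to -1.22 ± 0.24 (Mtp). These values, already seen when weighed, argue against a lower share as the whole account for this list. They do not exclude it as a part. Midgut tissue may have contributed to the protease rise. Of the 17 genes of the midgut protease list 58.8% (10) had a ratio to shared-barcode wild type within 2-fold of the ratio of the sums, 4.08. But ratios ran from 1.98 to 66.1, 6 of the 7 others averaging under 1 FPKM in wild type. This midgut test replaced 2 earlier ones, a count of the proteases that only restated the pattern and a count of maltases (2 of 2 higher) chosen with their values known. An effect of the knockdown on high-sugar larvae, in growth, stage or tissue, stays open beside them with 2 libraries. A difference in how these 2 libraries were made cannot be told apart from it. Both carry a barcode that no other group has, but so do replicates 1 to 3 of every other group. The Spearman correlations of the 2 high-sugar knockdown libraries with transcript length, -0.48 and -0.50, were the lowest of all libraries.

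The second pattern is the rise of the Hsp70B copies in the knockdown on the control diet. A heat shock response would raise other inducible heat shock genes, and 0 of the 8 other heat shock genes and cochaperones tested with limma were called higher, nor was any at an unadjusted p under 0.05 (Hsp23 at -0.86 and Hsp83 at 0.23). Reads from vector sequence may account for the rise, since UAS vectors carry part of an Hsp70 promoter region and the marker gene white. With no filter white was higher by 0.45 ± 0.08 (limma adjusted p = 0.0048), from 0.403 ± 0.152 FPKM (SD, n = 6) to 0.799 ± 0.245 (SD, n = 3), below the filter used elsewhere. The knockdown larvae carry an additional construct, which could raise white whatever the source of the Hsp70B reads, so white does not decide the question. The wild-type larvae carry transgenes too, and whether any read came from a vector was not analysed here.

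The third pattern is the difference in the wild-type sugar effect between the barcode sets. Library scaling as the whole account would remove most of it, but 378 genes differed under quantile normalization, and 443 with the length trend removed. A difference in stage or in dissected tissue between the sets stays open and was not tested, though glue and cuticle sums differed between the sets, and midgut sums did on high sugar. The labels name no difference between the sets beyond the barcodes, so no biological explanation was tested.

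Other splits of the libraries were compared with the real ones. For sugar in wild type 1 of 100 splits, the real one, gave as many as 370 genes and the highest other gave 199, so a random split can be excluded as the source of the count; a split by barcode set, fitted without the set term, called 1165 genes, which points to a structure of the samples. For the knockdown on the control diet 3 of 84 splits gave at least 134 genes, but the other 2 follow the barcode set and called more: the own-barcode wild-type libraries against the rest 367 and the shared-barcode wild-type libraries 171. These splits therefore do not set the knockdown apart from a structure of the samples. With the own-barcode libraries left out the comparison called 135 genes. In the 6 shared-barcode control-diet libraries fitted alone the real split called 83 and the highest of the other splits 2, with 1 of 10 splits, the real one, as large, which is too few splits for a share under 0.05.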

How the results depend on the processing

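The fits with a mean for each group and set, the removals of the length trend, the filters at a mean of 0.1 and the fit without both high-sugar knockdown libraries were chosen only after the results were seen, and all other settings were planned. Over all settings, 7646 values of single genes kept direction and side of the threshold, 229 lost the call, 26 gained it and 22 reversed, and for lists the counts were 136, 57, 0 and 3. For each setting not named, the 5 counts stayed within 1.5 times those reported. Depth is unknown, so what it limits cannot be given.

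With a minimum mean of 5, where 754 genes were tested, the counts were 142, 70, 472, 485 and 413 in the order of the report, and with no filter, where 9696 were tested, the last 4 were 242, 3982, 3996 and 3068. A minimum mean of 0.1 (6869 tested) gave 219, 3531, 3494 and 2878 for the same 4, and with a pseudocount of 0.1 as well 3427, 3451 and 2886 for the last 3. For sugar in wild type the count was 167 without the set term, 78 with wild-type replicates 4 to 6 left out (53 of them among the 370), 563 with a mean for each group and set and 632 with the length trend also removed. For the knockdown on the control diet the last 2 gave 239 and 245. Apart from the changes in the number of genes and libraries tested, the cause was not tested. Upper quartile scaling moved the median log2 change for sugar in the knockdown from 0.01 to -0.10.

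Of 115 list tests 28 were called, 0 with an estimated correlation and 50 with fry. The slope of sugar effects was 0.986 with genes called in replicates 4 to 6 and effects from replicates 1 to 3, 0.563 and 0.761 with pseudocounts of 0.1 and 5, 0.755 with the replicate block and 0.771 with the length trend removed, and r was 0.375, 0.430, 0.530, 0.580 and 0.515, and 0.477 with quantile normalization. The cause was not tested.

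These values reversed, and the cause was not tested. Cg25C, never called in the report, was at -0.12 for sugar in wild type with replicates 4 to 6 left out; for the knockdown on the control diet at -0.26 without the set term, -0.11 with replicates 4 to 6 left out, -0.11 with a mean for each group and set, -0.15 with the length trend also removed and -0.11 with only the compared groups; on high sugar at 0.61 and 0.89, for sugar in the knockdown at 0.84 and 0.84, and for the interaction at 0.48 and 1.03, with the length trend removed alone and with set means, the last of each pair being called (adjusted p = 0.015, 0.019 and 0.038). Leaving out 1 library at a time it ranged from -0.18 to 0.31 on the control diet and from -0.42 to 0.076 for sugar in the knockdown, the reversed values being those without knockdown replicate 2 on the control diet. With the length trend removed and set means CG3523 was at 0.10 in the high-sugar knockdown, though its mean FPKM was lower there than in wild type. For sugar in the knockdown dmondo was at 0.016 with quantile normalization and 0.60 and 0.60 with the length trend removed alone and with set means, and its interaction was then 0.12 and 0.20. The mean FPKM of dmondo in the knockdown was lower on high sugar. Without the set term Lcp4 was at 0.76, Lcp3 at 0.070 and the cuticle list at an adjusted p of 0.931 on the control diet. With wild-type replicates 4 to 6 left out the ribosomal list (adjusted p = 0.145) and the Malpighian list (adjusted p = 0.254) turned direction in wild type.

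Leaving out 1 library at a time, with a lone high-sugar knockdown library assumed to vary like the other groups, gave counts of 256 to 405, 79 to 135, 1115 to 1479, 1089 to 1463 and 916 to 1246, a slope of 0.658 to 0.781 and r of 0.492 to 0.530. The count of 79 was without knockdown replicate 3 on the control diet, and so were the lost calls of CG5697 (adjusted p = 0.101) and Eip55E (0.0588). Without high-sugar knockdown replicate 1 the calls of CG31789 (0.0690) and sugarbabe (0.0737) against wild type and of noncoding_12767 (0.0677) were lost, and without replicate 2 those of bigmax (0.0771), Gpdh (0.0603) and AcCoAS (0.0595) with sugar in the knockdown. Calls of several genes near the threshold were lost without any of several libraries: in wild type CG6188 (11 libraries), daw (10), CG3523 (8), Lsp1gamma (5), CG31698 (4) and CG15917 (4); on the control diet Lcp4 (7), cbt (4), Lcp3 (3) and PyK (2); with sugar in the knockdown Sgs3 (11) and desat1 (2); in the interaction CG34296 (10) and CG12310 (3). Calls were gained by Dro (3 libraries), AttA (1, wild-type high-sugar replicate 5) and sugarbabe (1, wild-type high-sugar replicate 4) on the control diet and by bigmax (2) in the interaction.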

Other observations

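The removal of the length trend was chosen only after the results were seen, and the other list values come from the planned tests.

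In the trehalose, glycogen and sugar transport list 5 of 8 genes fell and none rose in the high-sugar knockdown against wild type (5 adjusted over the list alone, camera adjusted p = 0.11), with UGP, which makes UDP-glucose, at -0.91 ± 0.22 and Pgm at -0.80 ± 0.22, and with the length trend removed none was called and the list median went from -0.74 to -0.15 (adjusted p = 0.67). In glycolysis 1 of 12 rose, Pgk at 0.65 ± 0.14, and 3 fell, including Pgi at -1.12 ± 0.31, not called with the length trend removed (adjusted p = 0.091) (1 and 3 adjusted over the list alone, camera adjusted p = 0.80), and with that trend removed 2 were higher and 2 lower. With sugar in the knockdown 6 glycolysis genes rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.21), with Eno at 1.18 ± 0.30, PyK at 0.73 ± 0.12 and Hex-A at -0.52 ± 0.16, the last not called with the length trend removed (adjusted p = 0.66), and 8 of 18 lipolysis and oxidation genes rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.21), with scu at 1.29 ± 0.24 and yip2 at 1.24 ± 0.29. With the length trend removed 12 lipolysis and oxidation genes rose and 1 fell, and the median went from 0.32 to 0.65 (camera adjusted p = 0.030). That list was not called with an estimated correlation, which was used only with the trend left in. In the pentose phosphate and NADPH list 3 of 6 genes were higher and 1 lower in the high-sugar knockdown than in wild type (3 and 1 adjusted over the list alone, camera adjusted p = 0.28), with Tal at 1.46 ± 0.27.

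Of 8 ecdysone response and stage genes 1 was higher and 5 lower in the high-sugar knockdown than in wild type (1 and 5 adjusted over the list alone, camera adjusted p = 0.41), with the ecdysone receptor EcR at -0.61 ± 0.13, Eip74EF at -0.98 ± 0.15, broad (br) at -1.30 ± 0.29 and Eip55E at 1.25 ± 0.24, and with the length trend removed 2 were higher and none lower, EcR at 0.37 (adjusted p = 0.0078), and the list median went from -0.70 to 0.16. The kinase Akt1 was at -0.82 ± 0.12, not called with the length trend removed (adjusted p = 0.81), and the activin ligand daw at -1.31 ± 0.21. Of the hemocyte markers the scavenger receptor croquemort (crq) was at -1.39 ± 0.15 with sugar in the knockdown.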
